A study of Homo sapiens with 12 samples.

How the data were processed

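RNA sequencing counts were analysed for BE2C cells, a human neuroblastoma line in which the oncogene MYCN is amplified. Cells with intact LIN28B (WT) were compared with LIN28B knockout cells (KO). LIN28B is an RNA-binding protein that blocks the maturation of let-7 microRNAs. The 12 libraries fell into 4 groups of 3, WT and KO in each of 2 library sets. Per the labels' protocols, RNA was purified with Trizol and RNeasy Plus columns and made into paired-end libraries with a NEBNext Ultra II RNA kit. Polyadenylated RNA was selected in set 2, per the labels' protocols, and no selection is named for set 1. The KO libraries of set 2 carry the letters KO_WT in their titles, while their genotype label reads LIN28B knockout. The meaning of the added letters is not given in the sources used here, and the libraries were treated as KO. Libraries are named by group, set and number, as in WT_set1_1 and KO_set2_3.

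The deposited values were whole-number counts of reads per gene, not normalised, in 1 table per set with 26485 genes each. Per the file headers, the authors counted primary alignments over the exons of each gene with featureCounts 1.5.1 and a UCSC hg38 gene annotation. Neither paired-end counting nor a strand setting appears in the headers, so sense and antisense reads were not separated. In set 1, genes with exactly 2 counts outnumbered those with 1 by 1.69 to 2.16 times, the pattern left when both reads of a pair are counted. In set 2 this ratio was 0.524 to 0.560, which argues against counting both reads of most pairs. Whether its pairs were counted once or only 1 read of each was used stays open. Per the submitters' processing notes, Trimmomatic, Bowtie, TopHat and DESeq2 were also used, with hg38 as the genome. Because only the primary alignment of a multiply mapped read was counted, levels of genes with near-identical copies are uncertain, among them ribosomal protein genes with processed pseudogenes, histone genes and CD24. Levels of genes that overlap others on the opposite strand, such as MYCNOS opposite MYCN, are also uncertain. The header of the set 2 table names 9 libraries, of which 3 had no column and were not analysed here. Gene names were matched to a reference list of human genes, 23758 by current symbol and 1562 by an older one, while 1165 matched neither.

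Genes with enough counts were kept with the filterByExpr function of edgeR 4.0.16 (minimum count 10, minimum total 15) in R 4.3.3. Libraries were scaled with TMM factors, and levels are given as CPM on those scaled totals, from the cpm function of edgeR. KO was compared with WT within each set by edgeR's quasi-likelihood test on the 6 libraries of that set. A fit of all 12 libraries with a term for the set gave the change shared by both sets, and an interaction term gave the difference between the change in set 1 and that in set 2. P-values were adjusted by the Benjamini-Hochberg method, with 0.05 as the threshold. Log2 fold changes are KO minus WT, and errors are standard errors (SE) from the fit or standard deviations (SD) between libraries. Errors of list medians are SE from resampling the genes of a list as if they were independent. LIN28B and MYCN were also compared by a two-sided exact permutation test of their CPM. The labels do not say that the libraries came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. Nor do they say whether the KO libraries came from 1 clone or more. Other differences between the KO and WT cells thus cannot be told apart from loss of LIN28B. The knockout effect here means the difference between KO and WT libraries. Floors of detection cover counting error only, whereas SE from the fit and SD include the spread between libraries.

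A total of 41 gene lists with 1500 genes were written before the data were examined. They covered ribosomes and translation, let-7 and microRNA factors, MYC and MYCN targets, neuroblastoma cell identity, neuronal genes, adhesion and matrix, cell cycle and histones, metabolism, stress and signalling pathways, neighbours of LIN28B and markers of other cell types. Each list with 5 or more tested members was tested with camera from limma 3.58.1 at a preset correlation between genes of 0.01. The same test was run with the correlation estimated from the data, and with fry. For each list, genes past the threshold were counted with p-values adjusted over all genes, and again adjusted over the list alone. Overlaps between sets were tested with Fisher's exact test over the genes tested in both.

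Genes named in the text followed a rule also written before the data were examined. It took LIN28B and MYCN, the 6 protein-coding genes with the largest rise and the 6 with the largest fall in each set, 10 and 10 by their smaller change over both sets, up to 4 members of each list and comparison with the lowest p, and 5 and 5 for the difference between sets. The size-ranked parts required a mean of 5 CPM or more, and those within a set also required WT and KO libraries that did not overlap. The rule gave 273 genes. The comparisons, tests and alternatives were likewise chosen before the data were examined, except where stated.

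On simulated data with 200 changed genes, edgeR recovered 94.0% of the genes changed 2-fold in set 1, 82.1% in set 2, 98.5% over both sets and 80.6% for the difference between sets. At 1.5-fold these shares were 80.6%, 41.8%, 94.0% and 32.8%. In the simulated sets, 5.67%, 5.81%, 2.99% and 4.79% of the calls were unchanged genes. With DESeq2, run on the simulations of set 1 and of the difference, these shares were 9.62% and 16.5%. A simulated fall of the ribosome biogenesis list (log2 -0.3) was recovered by camera with a preset and with an estimated correlation, with 0 other lists called by either. Genes were simulated independently of each other, so this run cannot tell how either version performs on correlated genes. In the real data the estimated correlation within this list was 0.636 in set 1 and 0.398 in set 2.

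Alternatives were size factors by the median-ratio method (RLE), library totals without composition factors, no filter, a stricter filter (1 CPM in 3 libraries and a mean count of 50 or more), DESeq2 1.42.0, limma-voom, a required 2-fold change, totals without genes above 1% of counts, the replicate number as a block, 1 spread shared by all 12 libraries, and leaving out each library in turn. Total counts per library ranged from 69149581 to 139664331 in set 1 and from 25316586 to 45814083 in set 2. A count of 3, taken as the floor of detection, corresponded to 0.0215 to 0.0434 CPM in set 1 and 0.0655 to 0.118 CPM in set 2. These floors cannot be compared between the sets. Both reads of a pair seem to be counted in set 1 only, and 30.99% to 37.4% of its counts came from ribosomal RNA genes. Figures were drawn with matplotlib 3.10.9.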

Results

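Gene expression was measured by RNA sequencing in BE2C neuroblastoma cells with intact LIN28B (WT) or LIN28B knockout (KO), with n = 3 libraries per genotype in each of 2 library sets. Set 1 was made without a named selection of RNA, and set 2 from polyadenylated RNA. The total counts of set 1 were 139664331, 104422485 and 115855941 in WT and 79254308, 69547912 and 69149581 in KO. In set 2 they were 26469946, 38761130 and 25316586 in WT and 45543928, 43799349 and 45814083 in KO. Genes for ribosomal RNA took 30.99% to 37.4% of the counts in set 1 and 0.393% to 0.972% in set 2, and replication-dependent histone genes, whose mRNAs lack a poly(A) tail, took 0.578% to 0.767% and 0.0111% to 0.0181%. WT_set2_3 stood apart from the other two WT libraries of set 2, with 252 and 284 genes at least 2-fold apart. KO_set1_1 and KO_set2_1 stood apart from the other KO libraries of their sets, with 79 to 89 such genes per pair. The pairs WT_set1_2 with WT_set1_3 and KO_set1_2 with KO_set1_3 had 1 and 0 such genes, and WT_set2_1 with WT_set2_2 and KO_set2_2 with KO_set2_3 had 6 and 0. By chi-square statistics per degree of freedom, KO_set2_2 with KO_set2_3 and WT_set2_1 with WT_set2_2 differed least, at 1.84 and 3.35, against 8.84 to 45.7 for the other pairs within groups. The value for KO_set2_2 with KO_set2_3 lay above 1, which independent counts would give, but not above 2, which counting both reads of every pair would give. Set 2 showed no excess of genes with exactly 2 counts over those with 1 (ratio 0.524 to 0.560). The value for WT_set2_1 with WT_set2_2 lay above both. In KO_set2_2 and KO_set2_3 the ratio of genes with 2 counts to those with 1 was 0.553 and 0.549. This argues against counting both reads of most pairs there, and so against sampling noise alone as the source of the value of 1.84. These libraries were kept separate.

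LIN28B itself was lower in every KO library than in every WT library of its set. The gene lies on chromosome 6 from 104957048 to 105083332 on the plus strand of hg38 and has 4 exons with 5505 bases. In set 1 its level was 127, 128 and 125 CPM in WT and 37.2, 42.5 and 40.0 CPM in KO. In set 2 the levels were 178, 189 and 119 CPM in WT and 56.3, 64.0 and 63.7 CPM in KO. The mean fell from 127 ± 1.27 to 39.9 ± 2.65 CPM (SD, n = 3) in set 1, a log2 fold change of -1.67 ± 0.05 (SE; edgeR, adjusted p = 9.8e-06). In set 2 it fell from 162 ± 38.0 to 61.4 ± 4.36 CPM (SD, n = 3), or -1.40 ± 0.17 (SE; edgeR, adjusted p = 0.0063). KO libraries thus kept 31.5% and 37.9% of the WT level in reads over the whole gene, and the labels do not give the edited part. An exact permutation test gave p = 0.1 in each set, the smallest value that 3 against 3 libraries allow (n = 3).

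MYCN, the amplified driver oncogene of this line, also fell. It lies on chromosome 2 from 15940438 to 15947007 on the plus strand and has 3 exons with 3038 bases. Its mean fell from 3305 ± 160 to 2388 ± 381 CPM in set 1 (SD, n = 3), to 72.2% of WT, and from 5145 ± 44.1 to 3327 ± 489 CPM in set 2, to 64.7%. The log2 fold changes were -0.47 ± 0.10 and -0.63 ± 0.11 (SE; edgeR, adjusted p = 0.011 in each). The call in set 1 was lost without WT_set1_2. MYC, the paralog of MYCN, rose from a low level, from 1.62 to 3.90 CPM in set 1 and from 2.24 to 6.57 CPM in set 2 (log2 fold changes 1.27 and 1.57; edgeR, adjusted p = 0.00089 and 0.0061).

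**Figure D1:**
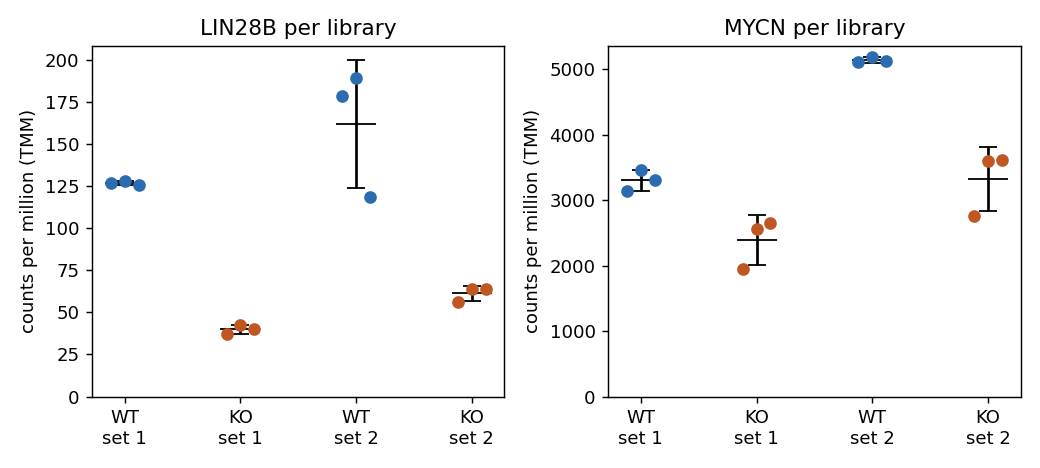
Levels of LIN28B and MYCN in CPM (TMM-scaled) in each library of the WT and KO groups of both sets, with 1 point per library, a horizontal bar for the mean and error bars for the SD (n = 3). LIN28B lay between 119 and 189 CPM in WT and between 37.2 and 64.0 CPM in KO.

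The first comparison asked how the transcriptome of KO cells differed from that of WT cells in set 1. Most genes that build ribosomes and replicate DNA were lower in KO, and some genes of neurons (24 of 52) and the extracellular matrix (19 of 46) were higher. Of 87 ribosome biogenesis factors tested, 77 fell, and of 43 genes of the G1/S phase, 37 fell. IGDCC3, a surface receptor of the immunoglobulin family, fell from 33.8 ± 3.3 to 7.86 ± 1.7 CPM (SD, n = 3). NGFR, the low-affinity neurotrophin receptor, rose from 1.15 ± 0.18 to 9.22 ± 6.0 CPM, and NAV2, a cytoskeletal regulator of neurite growth, rose from 8.34 ± 2.1 to 78.7 ± 52 CPM.

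In set 1, 5835 of 17078 genes tested changed (34.2%), of which 2854 rose and 2981 fell (edgeR). With library totals alone, which moved the median of all genes from a log2 fold change of 0.0226 to 0.168, 5137 genes rose and 724 fell. Most changes were small, since 591 of the genes that rose and 67 of those that fell changed at least 2-fold. WT and KO libraries did not overlap for 8831 genes (51.7%), where chance gives 10%. Among called protein-coding genes with a mean of at least 5 CPM and no overlap between WT and KO libraries, the largest rises were those of DLG2, a synaptic scaffold protein (log2 fold change 4.12 ± 0.91 SE, adjusted p = 0.011), NAV2 (3.23 ± 0.43, adjusted p = 0.0019), CRABP2, a carrier of retinoic acid (3.01 ± 0.70, adjusted p = 0.013), NGFR (3.01 ± 0.42, adjusted p = 0.0022), the phosphatase PTPRH (2.54 ± 0.68, adjusted p = 0.022) and the sphingosine receptor S1PR1 (2.38 ± 0.45, adjusted p = 0.0059). DLG2 was at 89.5 CPM in KO_set1_1 and at 11.6 and 9.19 CPM in the other KO libraries. Without KO_set1_1 the log2 fold changes were 2.28 for DLG2, 1.57 for CRABP2, 1.11 for PTPRH and 1.57 for S1PR1. The calls for DLG2 and CRABP2 were lost without WT_set1_2 or WT_set1_3, that for PTPRH without any of the WT libraries of set 1, and all of these with voom.

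Under the same limits, the largest falls in set 1, apart from LIN28B, were those of IGDCC3 (log2 fold change -2.11 ± 0.15 SE, adjusted p = 0.00021), the subunits GABRA4 and GABRB1 of the GABA-A receptor (-1.79 ± 0.28 and -1.65 ± 0.28, adjusted p = 0.0030 and 0.0042), SH3TC2 (-1.55 ± 0.28, adjusted p = 0.0051) and the homeobox gene LHX9 (-1.53 ± 0.18, adjusted p = 0.0013; edgeR for each). Their calls held with each library of set 1 left out in turn. The number of genes called in set 1 fell to 3188 without WT_set1_2 and to 3101 without WT_set1_3.

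The second comparison put the same question to polyadenylated RNA in set 2. Most ribosomal proteins, ribosome biogenesis factors and replication genes were lower in KO, and some genes of neurons (15 of 53) and of mesenchymal identity (8 of 33) were higher. Among ribosomal proteins, 38 of 47 in the large subunit and 28 of 33 in the small subunit fell. CD99, a membrane glycoprotein, rose from 0.745 ± 0.27 to 13.1 ± 1.1 CPM (SD, n = 3). IRX6, a homeobox gene, fell from 19.8 ± 4.5 to 4.18 ± 1.1 CPM, and SHOX2, another homeobox gene, fell from 170.2 ± 8.6 to 46.5 ± 12 CPM.

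In set 2, 3475 of 15339 genes tested changed (22.7%), of which 1709 rose and 1766 fell (edgeR). With library totals alone, 2369 rose and 920 fell, and the median of all genes moved from 0.0293 to 0.112. Changes of at least 2-fold were found for 557 genes that rose and 92 that fell. WT and KO libraries did not overlap for 7254 genes (47.3%, against 10% by chance). When all 12 libraries shared 1 spread, 5500 of 17046 genes were called in set 2. Among called protein-coding genes with a mean of at least 5 CPM and no overlap in set 2, the largest rises were those of DLG2 (log2 fold change 4.62 ± 1.03 SE, adjusted p = 0.023), NGFR (4.19 ± 0.57, adjusted p = 0.0070), CD99 (4.17 ± 0.21, adjusted p = 0.0015), CRABP2 (3.33 ± 0.90, adjusted p = 0.040), the actin-bundling protein LCP1 (3.12 ± 0.50, adjusted p = 0.010) and DUSP6, a phosphatase that limits ERK signalling (3.04 ± 0.64, adjusted p = 0.019). CD99 is annotated on both sex chromosomes, so its counts are uncertain. Under the same limits, the largest falls were those of GNG11 (-2.76 ± 0.55, adjusted p = 0.017), smooth muscle actin ACTA2 (-2.36 ± 0.48, adjusted p = 0.017), IRX6 (-2.24 ± 0.24, adjusted p = 0.0049), HS3ST3A1 (-2.11 ± 0.13, adjusted p = 0.0029), HIVEP2 (-2.08 ± 0.14, adjusted p = 0.0029) and RTL1, a retrotransposon-derived imprinted gene (-1.90 ± 0.35, adjusted p = 0.014).

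Several of these calls in set 2 rested on single libraries. Those for DLG2 and DUSP6 were lost without WT_set2_1 or WT_set2_2, and that for CRABP2 without either of these, KO_set2_1 or KO_set2_2. With voom, the calls for DLG2 and CRABP2 were lost. Without KO_set2_1 the log2 fold change was 2.84 for DLG2 and 1.86 for CRABP2. The call for GNG11, at 29.9 CPM in WT_set2_3 and 8.05 and 8.10 CPM in the other WT libraries, was lost without any of the KO libraries, and that for ACTA2 without any library of set 2 except WT_set2_3. Every library of set 2 moved the count of called genes by more than 1.5 times, to 855, 1196 and 6386 without WT_set2_1, WT_set2_2 and WT_set2_3, and to 1893, 1067 and 1448 without KO_set2_1, KO_set2_2 and KO_set2_3. When the closest pairs were summed (WT_set2_1 with WT_set2_2, and KO_set2_2 with KO_set2_3), a choice made after seeing the data that left 2 samples per genotype, edgeR called 0 genes, with 3393 at an unadjusted p under 0.05, voom called 0 and DESeq2 965.

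The third comparison asked which changes both sets shared. IGDCC3, LHX9, SHOX2 and SEMA6A, a transmembrane semaphorin, fell in both sets, and SCUBE1, LTK and NGFR rose in both. SCUBE1, a secreted and membrane-bound protein, rose from 10.5 ± 0.20 to 46.0 ± 14 CPM in set 1 and from 12.2 ± 3.9 to 56.3 ± 17 CPM in set 2 (SD, n = 3). LTK, a receptor kinase related to ALK, rose from 10.2 ± 1.2 to 34.3 ± 9.7 CPM and from 12.3 ± 4.2 to 63.2 ± 22 CPM. SEMA6A fell from 64 ± 5.6 to 26 ± 7.9 CPM and from 70.6 ± 4.6 to 25.2 ± 8.1 CPM.

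Over all 12 libraries, 7288 of 17046 genes changed, 3205 upward and 4083 downward (edgeR). With library totals alone, 5885 rose and 1399 fell. Among 15141 genes tested in both sets, 1068 rose in both, where independent lists give 297, and 1169 fell in both, where independent lists give 342 (odds ratios 12.6 and 12.9 by Fisher's exact test). Opposite calls were found for 13 genes up in set 1 and down in set 2 and for 28 the other way. Across genes, which are not independent replicates, the log2 fold changes of the sets correlated with Pearson's r of 0.716 and Spearman's rho of 0.675, and 76.5% had the same sign. KO library 1 deviated from its group mean alike in the sets, with r of 0.907 across 10889 genes. KO libraries 2 and 3 gave 0.732 and 0.725 with the same number in the other set, whereas WT libraries 1, 2 and 3 gave 0.111, -0.153 and -0.00018. Deviations within a group of 3 sum to 0, so a shared deviation of library 1 alone would make the values of KO libraries 2 and 3 positive. Those values therefore do not show that libraries 2 and 3 match by number. Over 10880 genes, the deviations of the KO libraries gave 6.81% of the covariance between the fold changes of the sets. Without KO library 1 of both sets, a choice made after seeing the data, 661 genes rose and 691 fell in both, and across 15288 genes Pearson's r was 0.611 and Spearman's rho 0.583, with a covariance of 0.105 against 0.153 with all libraries. The labels do not say whether the sets share RNA or cultures.

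Among protein-coding genes called in both sets, with a mean of at least 5 CPM and no overlap between WT and KO in each, the largest shared rises were those of DLG2, NGFR, CRABP2, NAV2, S1PR1 (log2 fold change 2.38 in set 1 and 2.81 in set 2), SCUBE1 (2.13 and 2.21), the protease PRSS12 (1.88 and 2.55), PLEKHA6 (1.86 and 2.19), LTK (1.74 and 2.36) and the integrin subunit ITGA1 (1.74 and 2.44). The shared falls were led by LIN28B, IGDCC3 (-2.11 and -1.55), SHOX2 (-1.51 and -1.87), GABRA4 (-1.79 and -1.51), LHX9 (-1.53 and -1.38), SEMA6A (-1.30 and -1.49), PCSK6 (-1.29 and -1.69), GABRB1 (-1.65 and -1.27), the adhesion protein FLRT3 (-1.47 and -1.20) and CAB39L (-1.12 and -1.07). NAV2, S1PR1, GABRA4, GABRB1, FLRT3, PLEKHA6 and ITGA1 lost their call in set 2 without WT_set2_1 or WT_set2_2, and PRSS12 lost it without WT_set2_1. NAV2 also lost it without any of the KO libraries, GABRA4 and FLRT3 without KO_set2_2, GABRB1 without KO_set2_2 or KO_set2_3, and PLEKHA6 without KO_set2_1 or KO_set2_2. In set 1, PLEKHA6 and ITGA1 lost their calls without any of the WT libraries. Without KO_set1_1 the fold changes were 1.24 for PRSS12, 0.92 for PLEKHA6 and 0.83 for ITGA1, and without KO_set2_1 they were 1.25 for PLEKHA6 and 1.56 for ITGA1.

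**Figure D2:**
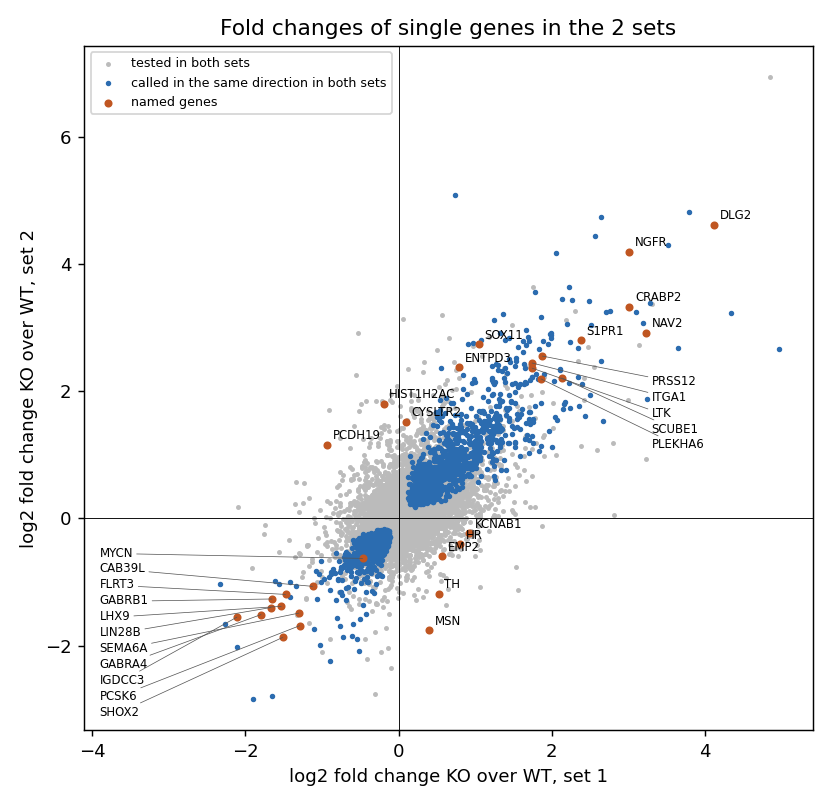
Log2 fold change KO over WT in set 1 (x axis) against set 2 (y axis) for the genes tested in both sets, with grey points for all of them, blue points for those called in the same direction in both sets and orange points with labels for named genes. The genes called in both sets, 1068 up and 1169 down, lie along the diagonal, and Pearson's r over all 15141 genes was 0.716.

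Of the 40 gene lists that could be tested, camera called 22 in set 1 (6 up and 16 down), 20 in set 2 (6 up and 14 down) and 21 over both sets. With an estimated correlation camera called 0 lists in each case, with 3, 2 and 9 lists at an unadjusted p under 0.05 and smallest adjusted p of 0.255, 0.419 and 0.168, while fry called 33, 17 and 27. Of the lists that camera called in set 2, fry did not call those of cholesterol and fatty acid synthesis, G1/S, glycolysis, let-7 targets, mesenchymal identity and small nucleolar RNA hosts. After a correction for exon length and GC content, a choice made after seeing the data, camera no longer called large-subunit ribosomal proteins, glycolysis and the interferon response in set 1, or oxidative phosphorylation and small nucleolar RNA hosts in either set. Without the filter, the interferon call in set 2 was lost.

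Many genes of ribosomes were lower in KO in both sets. Of 87 ribosome biogenesis factors, 77 fell in set 1 and 49 in set 2 (82 and 53 adjusted over the list alone), with median log2 fold changes of -0.32 and -0.31. By camera this list had adjusted p = 2.8e-21 and 7.0e-16, and adjusted p = 0.397 and 0.419 with an estimated correlation. BYSL, which acts in small-subunit assembly, fell from 41.5 ± 0.16 to 30.8 ± 0.79 CPM in set 1 and from 83.9 ± 1.2 to 59.7 ± 2.3 CPM in set 2 (SD, n = 3). MRTO4 fell by 0.53 and 0.49 on the log2 scale, NOP14 by 0.40 and 0.50, and PES1 by 0.36 and 0.45. Of 33 small-subunit ribosomal proteins, 25 fell in set 1 and 28 in set 2 (25 and 30 adjusted over the list alone), with medians of -0.18 and -0.32 (camera, adjusted p = 6.3e-08 and 8.9e-13, and adjusted p = 0.397 and 0.419 with an estimated correlation). Of 47 large-subunit proteins, 22 fell in set 1 and 38 in set 2 (22 and 43 adjusted over the list alone), with medians of -0.29 in set 2 and -0.13 in set 1, where the median turned to 0.016 with library totals alone and the median of all genes lay at 0.168. For the large subunit, camera gave adjusted p = 5.6e-06 and 4.4e-15, and adjusted p = 0.51 and 0.429 with an estimated correlation. RPS19 fell by 0.34 and 0.43, RPS3A by 0.28 and 0.45, RPL9 by 0.26 and 0.42, and RPL34 by 0.27 and 0.45 on the log2 scale, counts that processed pseudogenes make uncertain.

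Ribosomal proteins of mitochondria and translation factors fell in part, with fewer calls in set 2, where fewer simulated changes were recovered. The test of the difference between sets called 0 of 76 and 0 of 48 members. Camera on the difference gave adjusted p = 0.981 and 0.945. Of 76 mitochondrial ribosomal proteins, 47 fell, 1 rose and 28 did not pass the test in set 1, and 22 fell in set 2 (51 and 25 fell adjusted over the list alone), with medians of -0.21 and -0.19 (camera, adjusted p = 6.3e-14 and 1.1e-10, and adjusted p = 0.396 and 0.419 with an estimated correlation). MRPL14 fell by 0.45 and 0.50 and MRPL18 by 0.33 and 0.50 on the log2 scale. Of 48 translation initiation and elongation factors, 33 fell and 2 rose in set 1, and 18 fell in set 2 (38 and 25 fell and 2 and 2 rose adjusted over the list alone), with medians of -0.19 and -0.20 (camera, adjusted p = 4.6e-10 and 1.9e-06, and adjusted p = 0.396 and 0.419 with an estimated correlation). EIF3B, a core subunit of initiation factor eIF3, fell by 0.32 and 0.38. Of 29 host transcripts of small nucleolar RNAs and processed non-coding transcripts, 12 fell and 2 rose in set 1, and 9 fell and 3 rose in set 2 (16 and 2, and 11 and 5, adjusted over the list alone), with medians of -0.20 and -0.18. Camera gave adjusted p = 0.00052 and 0.033, with adjusted p = 0.396 and 0.626 with an estimated correlation, and the call in set 2 was lost without KO_set2_1. SNHG17 fell by 0.26 and 0.49, while the nuclear RNA MALAT1 rose by 0.40 and 0.81.

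Most targets of MYC and MYCN were lower in KO in both sets. Of 49 genes that MYC and MYCN activate, 46 fell in set 1 and 32 in set 2 (46 and 36 adjusted over the list alone), with medians of -0.30 and -0.33 (camera, adjusted p = 4.1e-15 and 2.3e-13, and adjusted p = 0.397 and 0.419 with an estimated correlation). The nucleolar methyltransferase FBL fell by 0.54 and 0.61, the helicase subunit MCM2 by 0.39 and 0.55, and the mitochondrial aminotransferase GOT2 by 0.42 and 0.39 on the log2 scale; the list shares such genes with the ribosome and replication lists.

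Known mRNA targets of let-7 leaned downward. Of 61 tested in set 1, 28 fell, 5 rose and 28 did not pass the test, and of 60 in set 2, 19 fell and 6 rose (29 and 20 fell and 6 and 7 rose adjusted over the list alone). The median was -0.13 in each set, and in set 1 it turned to 0.012 with library totals alone, where the median of all genes lay at 0.168. Camera gave adjusted p = 0.00083 and 0.018, and adjusted p = 0.255 and 0.419 with an estimated correlation. IGF2BP1, an oncofetal RNA-binding protein, fell from 183.4 ± 5.0 to 99.5 ± 3.7 CPM in set 1 and from 213 ± 33 to 119 ± 3.4 CPM in set 2 (SD, n = 3). HIC2 fell by 0.66 and 0.56, HMGA1, a chromatin protein, by 0.40 and 0.56, and the phosphatase CDC25A by 0.52 and 0.64 on the log2 scale. MYC, also on this list, rose. The list holds LIN28B itself, and without it, a choice made after seeing the data, 27 of 60 fell and 5 rose in set 1 and 18 of 59 fell and 6 rose in set 2 (28 and 19 fell and 6 and 7 rose adjusted over the list alone). The medians were then -0.11 and -0.10 (camera, adjusted p = 0.0019 and 0.028, and adjusted p = 0.261 and 0.419 with an estimated correlation).

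Most G1/S genes of the cell cycle were called lower in KO in both sets, and most G2/M genes were called lower in set 1 but not in set 2. By camera on the difference, the G2/M list had a lower change in set 1 than in set 2 (adjusted p = 0.0094). With an estimated correlation, that test called 0 lists. Of 43 G1/S genes, 37 fell in set 1 and 26 in set 2 (38 and 29 adjusted over the list alone), with medians of -0.28 and -0.43 (camera, adjusted p = 2.5e-12 and 3.6e-11, and adjusted p = 0.397 and 0.49 with an estimated correlation). UHRF1 fell by 0.39 and 0.77, UNG by 0.48 and 0.82, and GINS2 by 0.45 and 0.62 on the log2 scale. Of 54 G2/M genes, 34 fell in set 1 and 6 in set 2 (39 and 5 adjusted over the list alone), with a median of -0.20 in set 1 (camera, adjusted p = 2.8e-11, and adjusted p = 0.397 with an estimated correlation). In set 2 the median of the G2/M list was -0.065 (camera, adjusted p = 0.104). With library totals alone it turned to 0.020, where the median of all genes lay at 0.112. LBR, a receptor of the inner nuclear membrane, fell by 0.68 and 0.61, and CKS1B by 0.42 and 0.70. Of 53 replication-dependent histone genes, 47 fell in set 1 (48 adjusted over the list alone), with a median of -0.43 (camera, adjusted p = 1.2e-19, and adjusted p = 0.396 with an estimated correlation). Of 36 tested in set 2, 16 rose and 1 fell (17 and 1 adjusted over the list alone), with a median of 0.65 (camera, adjusted p = 7.2e-06, and adjusted p = 0.419 with an estimated correlation).

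Metabolic and proteostasis genes fell in part, with fewer calls in set 2, where fewer simulated changes were recovered. These lists were not among those that camera called for the difference between sets. Of 33 genes of cholesterol and fatty acid synthesis, 23 fell and 1 rose in set 1 and 11 fell in set 2 (26 and 1, and 12 fell, adjusted over the list alone), with medians of -0.26 and -0.31 (camera, adjusted p = 1.9e-09 and 1.0e-05, and adjusted p = 0.255 and 0.49 with an estimated correlation). The desaturase SCD fell by 0.46 and 0.69 and the acetyl-CoA carboxylase ACACA by 0.41 and 0.59 on the log2 scale. Of 40 genes of the ATF4 and amino acid response, 24 fell and 3 rose in set 1 and 10 fell and 2 rose in set 2 (27 and 4, and 10 and 2, adjusted over the list alone), with medians of -0.21 and -0.20 (camera, adjusted p = 5.6e-06 and 0.0017, and adjusted p = 0.396 and 0.419 with an estimated correlation). PSAT1, of serine synthesis, fell by 0.56 and 0.69, and the glutamine transporter SLC1A5 by 0.33 and 0.48. Of 74 nuclear genes of oxidative phosphorylation, 39 fell and 1 rose in set 1 and 14 fell in set 2 (40 and 1, and 13 fell, adjusted over the list alone), with medians of -0.14 and -0.15, the first of which turned to 0.0052 with library totals alone. With those totals the median of all genes in set 1 lay at 0.168. The test of this list by camera gave adjusted p = 2.4e-08 and 3.5e-08, and adjusted p = 0.396 and 0.49 with an estimated correlation. Of 26 glycolysis genes, 12 fell and 4 rose in set 1 and 5 fell in set 2 (14 and 4, and 5 fell, adjusted over the list alone), with medians of -0.14, which turned to 0.0027 with library totals alone, and -0.20. Camera gave adjusted p = 0.021 and 0.0017, with adjusted p = 0.51 and 0.523 with an estimated correlation, and the call in set 2 was lost without WT_set2_3. Of 20 heat shock and proteostasis genes, 14 fell in set 1 and 7 in set 2 (15 fell, and 8 fell and 1 rose, adjusted over the list alone), with medians of -0.21 and -0.26 (camera, adjusted p = 1.2e-05 and 0.0012, and adjusted p = 0.397 and 0.419 with an estimated correlation). The chaperones HSP90AB1 and HSPA8 fell by 0.27 and 0.30 in set 1 and by 0.48 and 0.39 in set 2.

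Genes of neurons, matrix and mesenchymal identity rose in part. Of 52 genes of neuronal differentiation and synapses tested in set 1, 24 rose and 6 fell, and of 53 in set 2, 15 rose and 1 fell (26 and 6, and 16 and 1, adjusted over the list alone). The medians were 0.18 and 0.25 (camera, adjusted p = 0.0031 and 0.00018, and adjusted p = 0.397 and 0.419 with an estimated correlation). The sodium channels SCN2A and SCN3A rose by 0.90 and 1.08 in set 1 and by 1.31 and 1.22 in set 2, and the neuropeptide galanin (GAL) by 0.95 and 1.73. Of 35 markers of mesenchymal neuroblastoma identity, 13 rose and 2 fell in set 1, and of 33, 8 rose in set 2 (14 and 2, and 8 rose, adjusted over the list alone). Their medians were 0.21 and 0.30 (camera, adjusted p = 0.0043 and 0.0050, and adjusted p = 0.396 and 0.49 with an estimated correlation), and the call in set 2 was lost without WT_set2_1 or KO_set2_1. FN1, or fibronectin, rose by 0.67 and 1.53 and the transcription factor TBX18 by 0.89 and 1.96. Vimentin (VIM) rose in set 1 (0.64) and gave 0.02 in set 2 (edgeR, adjusted p = 0.93).

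Of 62 genes of cell adhesion and migration, 27 rose and 8 fell in set 1, with a median of 0.27 (29 and 8 adjusted over the list alone; camera, adjusted p = 0.0048, and adjusted p = 0.397 with an estimated correlation). In set 2, 15 of 61 rose and 9 fell, with a median of 0.27 (23 and 10 adjusted over the list alone; camera, adjusted p = 0.138). The cadherin CDH10 rose by 1.03 and 1.35, and the integrin subunit ITGB5 fell by 0.35 and 1.14. Of 46 genes of the extracellular matrix, 19 rose and 5 fell in set 1, with a median of 0.32 (22 and 5 adjusted over the list alone; camera, adjusted p = 0.0031, and adjusted p = 0.396 with an estimated correlation). In set 2, 12 of 44 rose and 4 fell, with a median of 0.30 (15 and 6 adjusted over the list alone; adjusted p = 0.062 by camera and 0.030 by fry). The collagen COL4A2 rose by 0.99 and 2.15, and elastin (ELN) fell by 0.54 and 0.85.

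Signalling lists rose in part. Of 32 immediate early genes, 13 rose and 1 fell in set 1, with a median of 0.21 (14 and 1 adjusted over the list alone; camera, adjusted p = 0.0031, and adjusted p = 0.397 with an estimated correlation), and of 31 in set 2, 6 rose, with a median of 0.20 (10 rose and 1 fell adjusted over the list alone; camera, adjusted p = 0.16). DUSP2, a phosphatase of MAP kinases, rose by 1.65 and 1.25. Of 29 interferon response genes, 7 rose and 1 fell in set 1, and of 28 in set 2, 5 rose (6 and 1, and 5 rose, adjusted over the list alone), with medians of 0.31 and 0.38. Camera gave adjusted p = 0.042 and 0.012, with adjusted p = 0.396 and 0.419 with an estimated correlation, and the call in set 1 was lost without WT_set1_3 or KO_set1_2. STAT2, a transducer of interferon signals, rose by 0.81 and 1.05.

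Of the lists of markers of other cell types, camera called the epithelial and the immune one upward in set 2. Of 8 epithelial markers, 2 rose in set 2, with a median of 0.81 (3 adjusted over the list alone; camera, adjusted p = 0.022, and adjusted p = 0.49 with an estimated correlation), and of 15 in set 1, 3 rose, with a median of 0.45 (3 adjusted over the list alone; camera, adjusted p = 0.222). The tight junction gene CLDN4 rose from 3.35 to 5.04 CPM in set 1 and from 3.40 to 7.65 CPM in set 2. Of 5 immune cell markers, 2 rose in set 2, with a median of 0.55 (3 adjusted over the list alone; camera, adjusted p = 0.034, and adjusted p = 0.419 with an estimated correlation). They were CD4, from 0.667 to 1.04 CPM, and LYZ, from 2.39 to 3.33 CPM, calls that were lost without any library of set 2 except WT_set2_3, without the filter and with DESeq2, and that of LYZ also with RLE factors. In set 1, 7 of 7 immune markers did not pass the test, with 1 at an unadjusted p under 0.05 (edgeR) and a median of 0.36 (camera, adjusted p = 0.764). The epithelial call in set 2 was lost without WT_set2_2 or WT_set2_3, and the immune call without KO_set2_1.

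**Figure D3:**
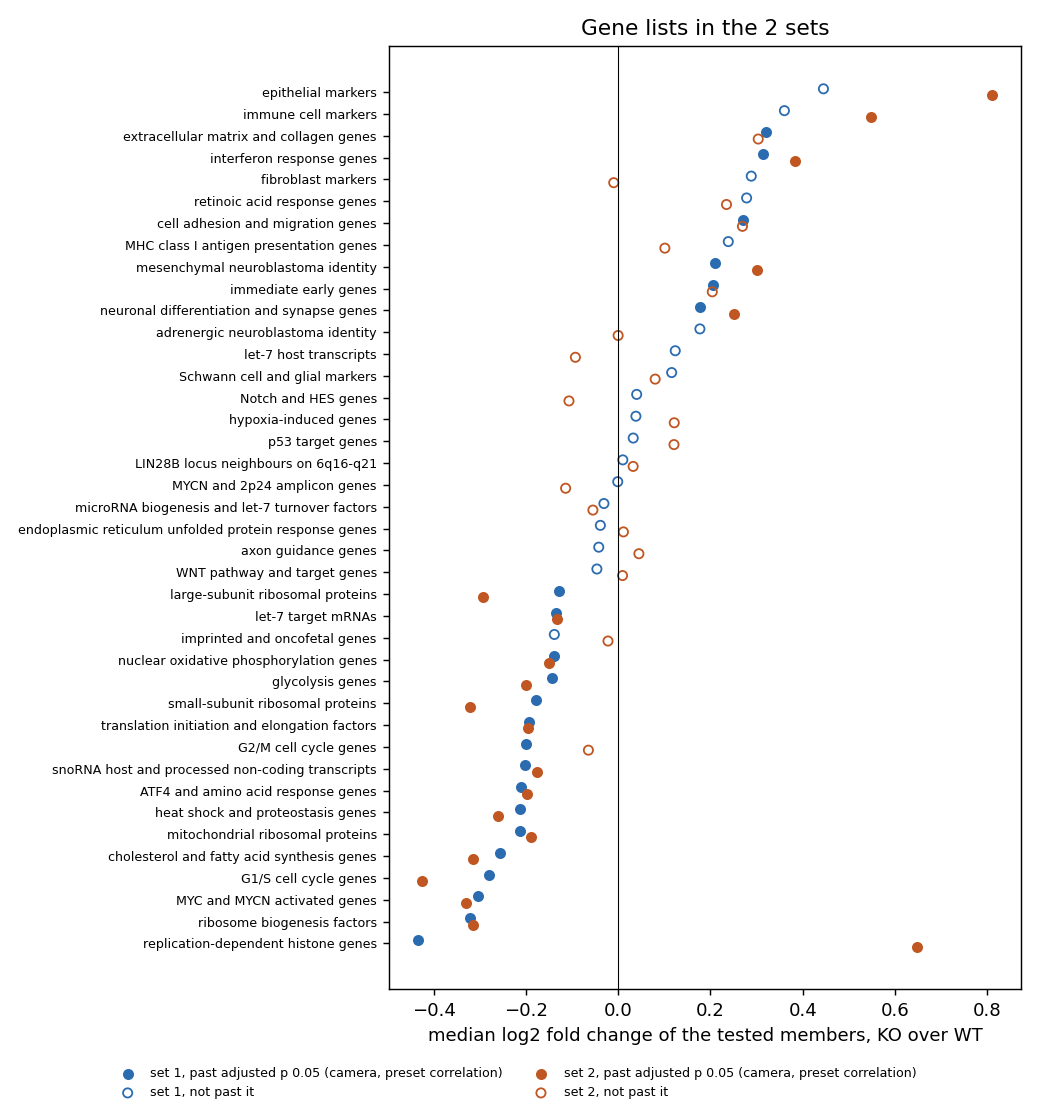
Median log2 fold change KO over WT of each gene list (x axis) in set 1 (blue) and set 2 (orange), with filled points for lists past an adjusted p of 0.05 by camera at the preset correlation and open points for the others. Ribosome biogenesis factors lie at -0.32 and -0.31 and histone genes on opposite sides, at -0.43 and 0.65. With library totals alone the medians of large-subunit ribosomal proteins, let-7 targets, oxidative phosphorylation and glycolysis in set 1 and of G2/M genes in set 2 turn positive. The median of all genes is then 0.168 in set 1 and 0.112 in set 2.

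The fourth comparison asked where the effect of the knockout differed between the sets. Of 53 histone genes 47 fell in set 1, and of 36 in set 2, 16 rose, 1 fell and 19 did not pass the test. Single genes such as MSN, TH and PCDH19 moved in opposite directions. MSN, or moesin, which links actin to the membrane, rose from 27.4 ± 2.6 to 36.3 ± 2.6 CPM in set 1 (SD, n = 3) and fell from 219 ± 115 to 64.8 ± 7.1 CPM in set 2. TH, the rate-limiting enzyme of catecholamine synthesis, rose from 18.9 ± 1.7 to 27.3 ± 1.4 CPM in set 1 and fell from 108 ± 53 to 47.6 ± 1.2 CPM in set 2, by 1.19 on the log2 scale and by 0.70 without WT_set2_3. PCDH19, a protocadherin, fell from 81.8 ± 2.2 to 42.8 ± 2.0 CPM in set 1 and rose from 22 ± 9.7 to 48.9 ± 3.8 CPM in set 2. For MSN, TH and PCDH19, the WT means lay farther apart between the sets than the KO means. For these genes, a WT level that differed between the sets cannot be told apart from a knockout effect that differed. CPM of the 2 sets are not on the same scale, which limits comparing levels between them. Scaling was done within each set, and ribosomal RNA took 30.99% to 37.4% of the counts in set 1 and 0.393% to 0.972% in set 2.

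The interaction term of edgeR called 214 of 17046 genes, 76 with a higher and 138 with a lower change in set 1 than in set 2. With library totals alone the split was 136 and 84, and DESeq2 called 739 genes, 409 higher and 330 lower. On simulated data, 16.5% of the DESeq2 calls for this difference were unchanged genes, against 4.79% with edgeR. Among called protein-coding genes with a mean of at least 5 CPM in each set, the largest positive differences were those of MSN (log2 difference 2.16 ± 0.37 SE, adjusted p = 0.017), TH (1.71 ± 0.34, adjusted p = 0.035), HR (1.20 ± 0.10, adjusted p = 0.00021), EMP2 (1.16 ± 0.11, adjusted p = 0.00059) and the potassium channel subunit KCNAB1 (1.15 ± 0.19, adjusted p = 0.015). Under the same limits, the largest negative ones were those of PCDH19 (-2.10 ± 0.29, adjusted p = 0.0054), HIST1H2AC (-2.00 ± 0.16, adjusted p = 0.00016), the transcription factor SOX11 (-1.71 ± 0.27, adjusted p = 0.012), ENTPD3 (-1.58 ± 0.24, adjusted p = 0.010) and CYSLTR2 (-1.43 ± 0.18, adjusted p = 0.0031). SOX11 rose in both sets, by 1.05 and 2.74, and ENTPD3 by 0.79 and 2.38. MSN was at 353 CPM and TH at 170 CPM in WT_set2_3, against 152 and 154 and against 76.8 and 78.5 CPM in the other WT libraries of set 2.

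The count of 214 fell to between 84 and 135 without any single library other than KO_set1_1, which left 182, and WT_set2_3, which left 1676. The calls for MSN were lost without any of the WT libraries of set 1, KO_set2_2 or KO_set2_3, those for TH without any library other than the WT libraries of set 2, those for KCNAB1 without any of the WT libraries of set 1 and that for SOX11 without WT_set2_1 or WT_set2_2. Within set 2, the fall of MSN was lost without KO_set2_2 or KO_set2_3, that of TH without WT_set2_1 or any of the KO libraries and that of HR without WT_set2_1, and the rise of PCDH19 was lost without any library except WT_set2_3.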

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

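The test of each list's difference between sets, the test of histone genes with each library left out and that of carry-over were chosen after the results were seen. Every result here was singled out because the effect of the knockout differed between the 2 library sets by a test of the difference itself, and differences are log2 fold changes of set 1 minus those of set 2. Groups of 3 libraries were too small for a test of single outlying samples.

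Replication-dependent histone genes differed most among the gene lists. The median difference over 53 genes was -0.92, and 19 genes passed the test (32 with a lower and 1 with a higher change in set 1 adjusted over the list alone). Camera on the difference gave adjusted p = 2.4e-21, and adjusted p = 0.189 with an estimated correlation. HIST1H4H differed by -2.30, HIST1H2BG by -2.28, HIST1H2AC by -2.00, HIST2H2BE by -1.37 and HIST2H2AC by -0.82 (edgeR, adjusted p = 0.00016 for the first 3, 0.00048 and 0.025). In set 2 the histone genes together took 0.0111% to 0.0136% of the counts in WT and 0.0166% to 0.0181% in KO, while in set 1 they took 0.723% to 0.767% and 0.578% to 0.639%.

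Carry-over of RNA without poly(A) tails into the KO libraries of set 2 would raise histone and ribosomal RNA reads together. The mean share of the small non-coding RNAs without tails (7SL, 7SK and others) was instead lower in KO than in WT, with a log2 ratio of -1.75 ± 0.59 (SE). Ribosomal RNA genes together took a mean of 0.724% of the counts in WT and 0.448% in KO. The share of RNA45S5 among them did not fall, with means of 0.0662% and 0.0671%. A single deviating library of set 2 did not carry the rise, since the median was lowest without WT_set2_1, at 0.60, and highest at 0.76. Sequencing depth did not either, since the median over 33 genes was 0.73 after all libraries of set 2 were thinned to the smallest. What stays open is that set 2 counts histone transcripts that carry a tail or escaped selection, whereas set 1 counts those without, so the sets may measure different histone RNAs. No biological explanation was tested.

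The other lists that differed between sets were large-subunit ribosomal proteins (median difference 0.17; camera, adjusted p = 6.0e-10), small-subunit ribosomal proteins (0.13; adjusted p = 3.2e-06), G1/S genes (0.16; adjusted p = 0.00045), G2/M genes (-0.16; adjusted p = 0.0094) and genes of neuronal differentiation and synapses (-0.10; adjusted p = 0.038), each with adjusted p = 0.982 with an estimated correlation. Members that passed the test on their own were RPL35 of the large subunit (0.36; edgeR, adjusted p = 0.049) and 1 synaptic gene, which had a lower change in set 1 (4 and 1 adjusted over the list alone).

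The count of genes that differed was 214. Among named genes of adhesion and matrix, CD99 differed by -2.13, PCDH19 by -2.10, LUM by -1.19 and COL4A2 by -1.16, and MSN by 2.16, COL6A1 by 1.07, S100A4 by 0.88, ITGB5 by 0.79 and TIMP2 by 0.49 (edgeR, adjusted p from 0.00016 for ITGB5 to 0.034 for COL4A2). Among genes of the nervous system, SOX11 differed by -1.71, EPHA5 by -1.68 and SEMA3A by -0.87, and TH by 1.71 and KCNAB1 by 1.15 (edgeR, adjusted p from 0.0077 for EPHA5 to 0.035 for TH). The remaining named genes were ENTPD3 (-1.58), CYSLTR2 (-1.43) and GACAT3 (-0.66), and KLF2 (2.75), HS3ST3A1 (1.87), HIVEP2 (1.56), HR (1.20), EMP2 (1.16) and PFKFB3 (0.84; edgeR, adjusted p from 0.00021 for HR to 0.019 for KLF2). KLF2, a transcription factor, rose from 1.00 to 6.95 CPM in set 1 and was at 11.3 and 11.8 CPM in set 2.

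Splits of the 12 libraries gave as many genes as the real one in 4 of 100 cases, the real split included. This share cannot tell whether the count arose by chance, since genotypes cannot be exchanged freely where KO and WT differ in both sets. A split that mixes WT and KO within a group adds that difference to the spread between libraries. The labels also do not say that the libraries of the sets are independent. The highest of the other splits gave 7553 genes against 214. A split with that many genes points to a structure of the samples, since a split that exchanges WT and KO in 1 set turns the shared knockout effect into a difference between sets.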

How the results depend on the processing

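Alternatives chosen after the data were seen were the summed library pairs, leaving out KO library 1 of both sets with or without WT_set2_3, a random block for libraries of the same genotype and number (6887 genes over both sets with voom), the correction for length and GC, leaving LIN28B out of the lists that hold it and the list tests of the difference. No call of a named gene was reversed with RLE factors, no filter, DESeq2 (which gave DLG2 no adjusted p in either set), voom, the replicate block or 1 library left out. No list call was reversed with RLE factors, no filter, the block, 1 library left out, an estimated correlation, fry or the correction for length and GC. Medians of some lists turned with library totals or RLE factors. The fall of LIN28B held with each library left out, at -1.73 to -1.63 in set 1 and -1.58 to -1.28 in set 2. Requiring a 2-fold change left 658 genes in set 1, 649 in set 2, 672 over both sets, 77 for the difference and 273 for the overlap, by construction. With 1 library left out, the count ranged from 3101 to 6123 in set 1, from 855 to 6386 in set 2, from 6283 to 8130 over both sets and from 84 to 1676 for the difference. In set 2, 5500 genes were called when all 12 libraries shared 1 spread, and 0 by edgeR when the closest pairs were summed (3393 at an unadjusted p under 0.05; 0 by voom and 965 by DESeq2), where fewer samples remained and the fold changes correlated with the original ones at 0.991. DESeq2 called 739 genes for the difference, and leaving out KO library 1 of both sets left 1352 genes in the overlap of 2237. Apart from the 2-fold limit and the smaller numbers of samples, the cause was not tested. Camera with an estimated correlation called 0 lists in set 1 and 0 in set 2, with 3 and 2 at an unadjusted p under 0.05, and 0 for the difference, with 1 at an unadjusted p under 0.05. At the preset correlation, lists called ranged from 21 to 23 and from 17 to 22 with 1 library left out, and were 19 and 18 after the correction for length and GC, which kept 17 of 22 calls in set 1 and 16 of 18 in set 2. With LIN28B left out of the lists, camera called the same 22 and 20. Fry kept 22 of 22 calls in set 1 and 14 of 20 in set 2.

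The replicate numbers did not pair WT with KO, as deviations of libraries with the same number correlated at 0.27, 0.04 and 0.18 in set 1 and at -0.10, 0.14 and -0.07 in set 2, and 2 of 3 and 1 of 3 numbers correlated best with their own. With the number as a block, 1548 genes were called in set 2, 50 for the difference and 1220 for the overlap, and calls of named genes were lost for 3 of 230 in set 1, 44 of 192 in set 2, CRABP2 and NAV2 among them, and 3 of 10 for the difference. RLE factors, library totals, no filter, the stricter filter, voom and totals without abundant genes kept the counts of genes in set 1, in set 2, over both sets and for the difference within 1.5 times. Of 1380 calls of named genes in set 1 with 1 library left out, 105 were lost, and of 1152 in set 2, 283 were lost. At 1.5-fold, 41.8% of simulated genes were recovered in set 2 and 80.6% in set 1. Set 2 had a larger biological coefficient of variation (0.128 against 0.0873). It also had fewer counts, but both reads of a pair seem to be counted in set 1 only. Leaving out ribosomal and small non-coding RNA, libraries had 40381798 to 79668867 counts in set 1 and 25059003 to 45568113 in set 2. Whether set 2 held fewer usable read pairs thus stays open, and the parts of depth and spread were not separated.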

Other observations

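The test of depth for the ribosome lists, those of length and GC for ribosomal proteins and MYC targets, both tests on KO library 1 and the test of LIN28B neighbours without LIN28B were chosen after the results were seen, and LIN28B was taken out of the test of let-7 sites after a first run, which gave the same outcome with it.

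Several gene groups fixed in advance were not called by camera, though fry called the adrenergic list upward in both sets (adjusted p = 0.015 and 0.012) and the WNT list upward in set 1 (adjusted p = 0.013). Among 39 markers of adrenergic neuroblastoma identity, 16 rose and 7 fell in set 1 and 7 rose and 3 fell in set 2 (17 and 8, and 10 and 4, adjusted over the list alone; camera, adjusted p = 0.276 and 0.622), with a median of 0.18 in set 1 and, in set 2, a median of -0.00024 that turned positive with library totals alone and a mean of 0.13. GFRA2, a receptor of the neurturin family, rose by 1.59 and 1.65 on the log2 scale. Of 45 axon guidance genes in set 1, 13 rose and 14 fell, and of 43 in set 2, 8 rose and 8 fell (13 and 15, and 11 and 8, adjusted over the list alone; camera, adjusted p = 0.479 and 0.965). Their medians were -0.042, which turned positive with library totals alone, and 0.045 and their means 0.04 and 0.12, while camera pointed downward in each set. UNC5A and SLIT3 rose by 0.41 and 0.37 in set 1 and by 0.65 and 0.47 in set 2, and ROBO2 fell by 0.48 and 0.72. Of 25 and 24 genes of the retinoic acid response, 6 and 4 rose and 1 and 2 fell (6 and 5, and 1 and 3, adjusted over the list alone), with medians of 0.28 and 0.23 (camera, adjusted p = 0.152 and 0.45). In the Notch list of 20 genes, 4 rose and 6 fell in set 1 and 2 rose and 4 fell in set 2 (4 and 7, and 2 and 5, adjusted over the list alone), with medians of 0.040, where camera pointed downward, and -0.11 (camera, adjusted p = 0.95 and 0.217). DLK1 and JAG2, a pair of Notch ligands, fell by 0.97 and 0.76 in set 1 and by 0.96 and 1.69 in set 2, and HEY1, a Notch target, rose by 0.73 and 1.07. Among WNT genes, 6 of 29 rose and 4 fell in set 1, and 4 of 27 rose and 4 fell in set 2 (the same counts adjusted over the list alone), with medians of -0.046 and 0.0093, the first of which turned with library totals alone and the second with RLE factors, against means of 0.11 and 0.02 (camera, adjusted p = 0.866 and 0.881); the test pointed up in set 1 and down in set 2.

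Factors that make or destroy let-7 changed in part, and among the lists that follow camera called 0, while fry in set 1 called those of microRNA factors (adjusted p = 0.011) and imprinted genes (adjusted p = 0.030) downward and let-7 hosts upward (adjusted p = 0.028). Of 28 microRNA biogenesis and let-7 turnover factors, 5 rose and 9 fell in set 1 and 5 fell in set 2 (5 and 9, and 4 fell, adjusted over the list alone), with medians of -0.03 and -0.05 that turned positive with library totals alone (camera, adjusted p = 0.195 and 0.206). XPO5, which exports microRNA precursors, fell by 0.39 and 0.51, and DICER1 fell by 0.49 in set 1 and gave -0.17 in set 2 (edgeR, adjusted p = 0.53). Of 8 let-7 host transcripts, 4 rose and 1 fell in set 1 and 1 rose and 1 fell in set 2 (4 and 1, and 3 and 3, adjusted over the list alone), with medians of 0.12 and -0.093 and a mean of 0.07 in set 2 (camera, adjusted p = 0.348 and 0.97). MIR100HG, host of a let-7 cluster, rose by 0.90 and 1.40. Of 7 genes of the MYCN amplicon region, MYCN itself included, 1 rose and 3 fell in set 1 and 1 rose and 1, MYCN, fell in set 2, the same counts adjusted over the list alone, with medians of -0.0011, which turned positive with library totals alone, and -0.11, where the mean was 0.02 (camera, adjusted p = 0.764 and 0.927). Of 23 neighbours of LIN28B on chromosome 6, LIN28B itself left out, 3 rose and 5 fell in set 1 and 2 rose and 1 fell in set 2 (3 and 6, and 2 and 1, adjusted over the list alone), with medians of 0.019, where camera pointed down, and 0.040 (camera, adjusted p = 0.543 and 0.965; fry, adjusted p = 0.271 and 0.76). With LIN28B counted among its 24 members, as the list was fixed, 6 fell in set 1 and 2 in set 2 (camera, adjusted p = 0.298 and 0.927; fry, adjusted p = 0.022 and 0.984). BVES rose by 0.52 and 0.63. Of 20 imprinted and oncofetal genes, 4 rose and 7 fell in set 1 and 3 rose and 5 fell in set 2 (4 and 7, and 4 and 6, adjusted over the list alone), with medians of -0.14 and -0.02 that turned positive with library totals alone and a mean of 0.13 in set 2 (camera, adjusted p = 0.124 and 0.55).

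Camera did not call the stress lists or the marker lists that follow in either set. Fry called p53 targets upward in both sets (adjusted p = 0.039 and 0.018) and, in set 1, hypoxia (adjusted p = 0.028), MHC class I (adjusted p = 0.049), Schwann cell (adjusted p = 0.013) and fibroblast genes (adjusted p = 0.042). For 32 hypoxia genes, 7 rose and 6 fell in set 1 and 4 rose and 2 fell in set 2, the same counts adjusted over the list alone (medians 0.04 and 0.12; camera, adjusted p = 0.656 and 0.965). For 33 genes of the unfolded protein response of the endoplasmic reticulum, 3 rose and 7 fell in set 1 and 3 rose and 1 fell in set 2 (3 and 5, and 3 and 1, adjusted over the list alone), with medians of -0.039, which turned with library totals alone and had a mean of 0.0029, and 0.011, which turned with RLE factors (camera, adjusted p = 0.222 and 0.802). For 29 p53 targets, 8 rose and 4 fell in set 1 and 7 rose and 4 fell in set 2 (8 and 4, and 9 and 5, adjusted over the list alone), with medians of 0.03 and 0.12 (camera, adjusted p = 0.597 and 0.286); AEN fell by 0.55 and 0.66. For MHC class I genes, 2 of 12 rose in set 1 and 1 of 13 in set 2 (2 and 0 adjusted over the list alone; medians 0.24 and 0.10; camera, adjusted p = 0.148 and 0.587). For Schwann cell and glial markers, 5 of 18 rose and 2 fell in set 1 and 3 of 15 rose and 2 fell in set 2 (6 and 2, and 3 and 2, adjusted over the list alone; medians 0.12 and 0.08; camera, adjusted p = 0.427 and 0.622). For 14 fibroblast markers, 6 rose and 2 fell in set 1 and 2 rose and 2 fell in set 2 (7 and 2, and 4 and 4, adjusted over the list alone; camera, adjusted p = 0.141 and 0.965), with medians of 0.29 and -0.0098, the latter with a mean of 0.13 and turning positive with library totals alone. Of 13 mitochondrially encoded mRNAs, 0 were in the count tables.

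The lower levels of ribosome biogenesis, ribosomal protein and MYC or MYCN target genes in KO were weighed against technical causes by the medians of the lists, in the set nearer to 0. After a trend with transcript length and GC content was removed, the median was -0.28 ± 0.018 (SE) for ribosome biogenesis, -0.26 ± 0.026 for MYC and MYCN targets and -0.073 ± 0.028 for small-subunit proteins. The SE in this paragraph treat the genes of a list as independent and may be too small. The medians argue against that trend as the whole cause for ribosome biogenesis and for MYC and MYCN targets. For small-subunit proteins in set 1, where the remaining median is small, the trend stays open. For large-subunit proteins in set 1 the median moved from -0.13 ± 0.024 to -0.031 ± 0.026 and camera no longer called them, so the trend stays open as a cause there, while the median in set 2 was -0.18 ± 0.013. For ribosome biogenesis alone, the median was -0.26 ± 0.024 (SE) without KO library 1 of each set, and as total counts were higher in WT in set 1 and in KO in set 2, medians of -0.32 and -0.31 argue against depth. A lower MYCN level is a candidate cause that these data may fit but that was not tested apart from loss of LIN28B.

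KO_set1_1 and KO_set2_1 differed from the other KO libraries of their sets in the same direction, with r = 0.907 across 10889 genes. A bias by transcript length is argued against by the weak correlation of the deviation with exon length, with Spearman's rho of 0.0931 and 0.0794 in the sets. Admixture of WT RNA or cells into KO library 1 would pull the deviation against the knockout effect, but the slope of the deviation on the difference of KO libraries 2 and 3 from WT in the other set was positive, 0.261 ± 0.0063 (SE) and 0.452, so that KO library 1 lay farther from WT. No biological explanation was tested, and whether KO library 1 came from another clone, culture or RNA than KO libraries 2 and 3 stays open, as the labels do not say.

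If loss of LIN28B released let-7, mRNAs with a let-7 site would be expected to fall more than others, which was written down before the test. Of the protein-coding genes tested in both sets, LIN28B left out, 97.0% matched an annotated transcript. Among the 12466 of these with a 3' UTR of at least 50 bases, 462 held the let-7 site CTACCTCA. Matched for UTR length, their mean log2 fold change differed from that of genes without the site by -0.117 in set 1 and -0.110 in set 2. Medians, not matched for length, lay closer together, at -0.051 with and -0.0085 without the site in set 1 and at -0.018 and 0.0061 in set 2. Of 419 control sites of the same length, 0 gave a difference as low in either set (0%), the lowest being -0.076 and -0.081. The values are consistent with stronger let-7 repression in KO, as a hypothesis, since let-7 itself was not measured here.

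Splits of the libraries tested how far the counts of changed genes could arise by chance. In set 1 and in set 2, 1 of 10 splits, the real one, gave as many genes (5835 and 3475), and the highest of the other 9 gave 0 by edgeR, with 137 to 635 and 39 to 770 genes at an unadjusted p under 0.05; 10 splits are too few for a share under 0.05. Over both sets, 1 of 100 splits, the real one, gave as many as 7288 genes, the highest of the others giving 654. That excludes chance only if the libraries of the sets are independent. KO library 1 deviated alike in the sets, and if the sets shared samples, only 10 joint splits would exist, too few for a share under 0.05.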
